A study of Mus musculus with 14 samples.

How the data were processed

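Gene expression was measured in 14 mouse cell samples with Affymetrix expression arrays of 45101 probe sets, 1 array per sample. Per the labels, total RNA was prepared with TRIzol and labelled with biotin as cRNA. The deposited values are probe set summaries on the log2 scale, and per the submitters' processing notes they were made with RMA and the affy package. As a method, RMA corrects background, applies quantile normalization and summarises the probes of each probe set on the log2 scale. Versions and settings of these tools are not given in the sources used here.

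The deposited log2 values fell into 2 blocks of 7 arrays. The sorted values of the arrays differed by a median range of 0.085 within the first block and 0.096 within the other, against 0.318 over all 14 arrays. The first block held the untreated partial iPSCs, the 2i iPSCs, the embryonic fibroblasts and the ESCs, with array means of 6.09. The other block held the transduced 2B1 cells, with array means of 5.87 to 5.88. The blocks were treated as separately normalized. Tests were made within a block. Counts and levels set across the blocks, as with untreated 2B1 as a control for transduced arrays, are named as such where they are given. The filter on dim genes used all 14 arrays. On arrays, values near the lower end of the scale are background, and the number of arrays limits the precision. The lowest value of each array lay between 1.8 and 2.22 and the highest between 14.5 and 14.69.

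Probe sets were assigned to genes from the platform's annotation. Of the 45101 probe sets, 64 were controls, 34945 had exactly 1 gene, 932 had several genes and 9160 had none. Gene identifiers of 34754 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names and chromosomes only. No coordinates are given, because the files name no genome build. Each of the 18193 genes was represented by its probe set with the highest mean over the 14 arrays. Genes were tested if at least 2 of the 14 arrays reached the median of the whole table, 5.42 on the log2 scale. This left 12663 genes, and 5530 genes were left out as dim.

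The 3 groups with 2 arrays each were the untreated partial iPSCs, the 2i iPSCs and the ESCs. They were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 6 arrays, 3 residual and 2.25 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. The 2 arrays of a group came from separate clones or from separate lines, so p-values measure the spread between clones or lines, and no array was repeated within a clone. This spread was estimated over all 3 groups together, so it includes the group outside a comparison. The groups differed in it, with 219 genes at least 2-fold apart between the 2i iPSCs and 2002 between the ESC lines. The alternative with the 4 compared arrays alone leaves the other group out. The untreated and the 2i array of a clone are paired by the clone. Deviations from the group means of the same clone had a correlation of 0.11 across genes. The model without the clone was chosen before the data were examined, and a model with the clone as a replicate block was an alternative.

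Before the data were examined, 26 gene lists with 352 symbols were fixed. They covered naive pluripotency, general pluripotency, the reprogramming transgene genes, primed epiblast, fibroblast and mesenchymal genes, epithelial genes, ERK pathway feedback and targets, Wnt and beta-catenin targets, LIF and STAT3 targets, BMP and SMAD targets, the Ccr4-Not complex, other mRNA decay factors, germline genes, DNA methylation machinery, imprinted genes, p53 and senescence, and the interferon response. Markers of other cells were listed for two-cell-stage embryos, trophoblast, primitive and visceral endoderm, mesoderm, neural cells, muscle, and macrophages and blood. The last lists held X inactivation transcripts and Y-linked genes. Lists share some members, such as Klf4 and Dnmt3b. Lists with at least 3 tested members were tested with camera of limma at an inter-gene correlation of 0.01, two-sided and adjusted over the lists of a comparison, and again with an estimated correlation. Members past the gene test were counted with p adjusted over all genes and adjusted over the list alone.

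Conditions with 1 array have no replicates and no test. For the fibroblasts, the count was of genes at least 2-fold higher or lower than both partial clones. For each introduced factor, genes with a log2 difference of at least 1 from the empty vector array were counted. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. This percentile describes the arrays and is not a test of the condition. Genes with a log2 difference of at least 1 between the 2i and the untreated array of 5C5 were used to place the transduced arrays, with exact 95% binomial intervals. These intervals cover sampling of genes only, and genes are not independent. Correlations between arrays that share the vector control were set beside those of simulated unchanged arrays. Their spread per gene was set from the difference between the vector array and the Nanog array, the factor array closest to it. Shares of the ESC difference reached by 2i iPSCs were set beside 20 simulations, added after the shares were seen, in which ESCs kept their measured means and 2i iPSCs had those of partial iPSCs.

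Named genes were chosen by a rule fixed in advance. For each limma comparison these were the 10 highest and the 10 lowest log2 fold changes among called genes whose 4 differences between arrays had the same sign. For the single arrays they were the 5 highest and the 5 lowest differences. Introduced genes and members of the lists were named in addition. Genes named outside this rule are marked as chosen after their values were seen.

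The limma step was tested on simulated data for the comparison of 2i iPSCs with partial iPSCs over 12663 genes, with 200 changed genes in each of 5 runs. It recovered 2.4% of the genes changed by a log2 of 1, 64.2% of those changed by 2 and 89.1% of those changed by 3, and 6.2% of its calls were false. Of 200 simulated lists without a shift, 3.5% lay outside the middle 95% of random lists. Alternatives covered quantile normalization between the 14 arrays, centring each array on its median, other filters on dim genes, the mean of a gene's probe sets, eBayes with trend and robust, the 4 compared arrays alone, a 2-fold minimum, removal of X and Y genes, the clone as a block, leaving out each array, other controls and other gene sets for the conversion. Further alternatives, added after seeing the data, are named in the closing section. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.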

Results

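The series measured mRNA levels in mouse cells on the way to induced pluripotency. Partial induced pluripotent stem cells (partial iPSCs) are reprogrammed cells that stopped before the genuine pluripotent state. Clones 2B1 and 5C5, both female and C57BL/6, were kept in ordinary ESC medium, which holds serum and leukemia inhibitory factor (LIF), and gave 1 untreated array each. Each clone was also converted to iPSCs under 2i, a medium with inhibitors of MEK and GSK3, and gave 1 array each (2i iPSCs). Embryonic stem cells (ESCs) were of the Nanog-GFP line (male, C57BL/6) and of the EBRTcH3 line (male, 129sv), 1 array each, in LIF and serum. Mouse embryonic fibroblasts (MEFs) gave 1 array; their sample title gives 12.5 dpc and the series text 13.5 dpc. The other 7 arrays held 2B1 partial iPSCs with empty vector, Cnot1, Cnot2, Cnot3, Trim28, Cnot1, Cnot2 and Cnot3 together (the Cnot123 array), or Nanog, 1 array each. Cnot1, Cnot2 and Cnot3 are subunits of Ccr4-Not, a complex that removes poly(A) tails from mRNA, and Trim28 is a corepressor of transcription. Groups of 2 arrays are given as log2 RMA signal with SD and n, and fold changes as log2 with the standard error (SE) of the limma model.

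**Figure D1:**
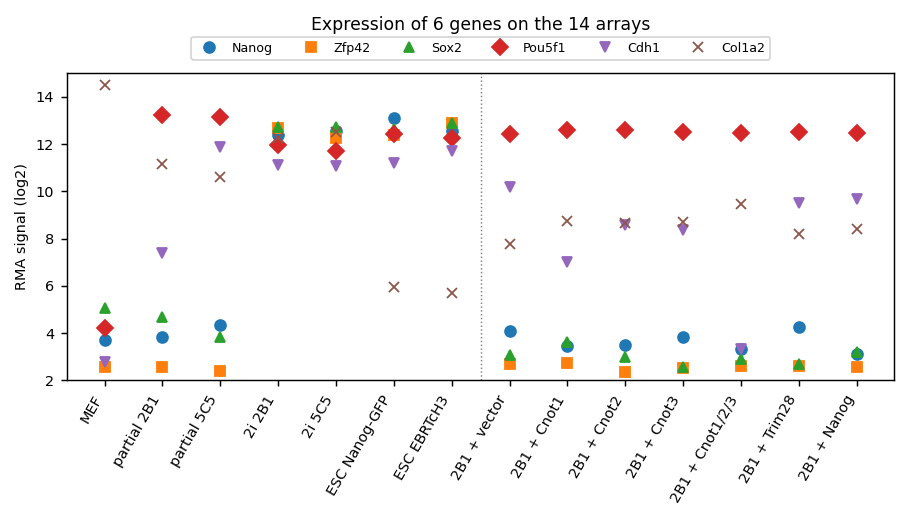
Log2 RMA signal (y axis) of Nanog, Zfp42, Sox2, Pou5f1, Cdh1 and Col1a2 on each of the 14 arrays (x axis), 1 point per array, with a dotted line between the 2 normalization blocks. Nanog lay between 12.38 and 13.12 on the 2i and ESC arrays and between 3.12 and 4.36 on the other 10 arrays.

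The first question was what changed when partial iPSCs were converted under 2i (n = 2 arrays against 2). Medium and state differ together here, so direct effects of the 2 inhibitors cannot be told apart from conversion. Zfp42, a marker of naive pluripotent cells, rose from 2.47 ± 0.14 (SD, n = 2) to 12.47 ± 0.30 (SE of the log2 fold change 0.27, limma adjusted p = 0.000551). Its level in partial iPSCs lay below the 25th percentile of the arrays (3.81 and 3.82), as did the lower mean of 9 of the 20 genes named by the rule, so the size and rank of such fold changes depend on the background. Nanog, a core transcription factor of pluripotency, rose from 4.11 ± 0.36 to 12.48 ± 0.14, by 8.37 (SE 0.30, adjusted p = 0.000869). Sox2, its partner in the core network, rose by 8.46 (SE 0.31, adjusted p = 0.000891). Slc38a5, an amino acid transporter, fell by 7.91 (SE 0.54, adjusted p = 0.00461). Hoxa9, a homeobox gene of the body axis, fell by 5.72 (SE 0.53, adjusted p = 0.00906).

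The other highest changes were of Rps4l (8.93), Trap1a (7.91), Mymx (7.87), Dppa2 (7.84), Dppa5a (7.74), Mageb16 (7.56) and Dazl (7.29). Dazl, a germ cell RNA-binding protein, differed more between the 2i clones than the others (SE 1.20, adjusted p = 0.0343), and lost its call with the clone as a block (adjusted p = 0.0755). The other lowest changes were of Sptssb (-7.09), Hbb-y (-7.03), Sbspon (-7.03), Gcnt3 (-6.77), Shisa3 (-6.30), Nt5e (-5.80), Clec2i (-5.79) and Fgfbp1 (-5.68). In all, 760 of 12663 tested genes were called, 449 higher and 311 lower under 2i (59.1% higher, and 385 and 387, or 49.9%, with arrays centred on the median), and each called gene had the same sign in all 4 differences between arrays. With the clone as a block the counts were 183 higher and 114 lower, and 37.9% of the called genes were called again. Without 1 array, the other array of its group is alone and is assumed to vary like the other groups. The counts were then 189 higher and 235 lower without untreated 2B1, 205 and 165 without untreated 5C5, 39 and 11 without 2i 2B1, 31 and 12 without 2i 5C5, and 847 and 549 without either ESC array. Of the 20 genes named by the rule, Dazl, Gcnt3, Shisa3, Nt5e and Hoxa9 lost their call without either 2i array (adjusted p from 0.0559 to 0.208), Dazl, Shisa3 and Nt5e without untreated 5C5, where Shisa3 had an adjusted p of 0.050, and Dazl without untreated 2B1 (adjusted p = 0.097).

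Of 20 naive pluripotency genes, 12 rose, 0 fell and 8 did not pass, and 15 rose with p adjusted over the list alone. They included Dppa4 (7.04, SE 0.24), Tcl1 (6.5, SE 0.36), Tbx3 (5.48, SE 0.39) and Esrrb (2.92, SE 0.31). The list was higher by camera (adjusted p = 8.61e-14), with adjusted p = 0.0764 with an estimated correlation. Of 16 general pluripotency genes, 6 rose and 1 fell, or 11 and 1 adjusted over the list alone. Lin28a rose by 6.44 (SE 0.49) and Gdf3 by 5.53 (SE 0.23), while Pou5f1 fell from 13.20 to 11.84 (log2 fold change -1.36, SE 0.19, limma adjusted p = 0.0233). The list was called higher (adjusted p = 5.1e-05; adjusted p = 0.194 with an estimated correlation). Of the 4 genes used as reprogramming transgenes, Sox2 rose, Pou5f1 and Myc fell (Myc -3.71, SE 0.24), and Klf4 did not pass (-0.73). This holds for the brighter probe set of Klf4 only: the other read 8.05 and 7.87 in the partial clones and 12.37 and 12.23 in 2i iPSCs. This list had a median of -1.05, a mean of 0.66 and a camera direction of down, and was not called (adjusted p = 0.221). The arrays do not separate transcripts of a transgene from those of the cell's own gene where their sequences are shared.

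Germline genes moved together. Of 15 tested, 11 rose and 0 fell, or 13 adjusted over the list alone, among them Tex19.1 (6.67, SE 0.50), Hormad1 (6.66, SE 0.71), a meiotic chromosome protein, and Ddx4 (4.64, SE 0.35), a germ cell helicase. The list was called (adjusted p = 6.54e-11; adjusted p = 0.377 with an estimated correlation). Of 10 genes of the DNA methylation machinery, Dnmt3l (5.48, SE 0.63), Tet1 (2.27, SE 0.27) and Dnmt3b (2.16, SE 0.36) rose and 0 fell, the same count of 3 adjusted over the list alone (adjusted p = 0.00544; adjusted p = 0.355 with an estimated correlation). Of 16 imprinted genes, Meg3 (4.92, SE 0.67), a noncoding RNA of the Dlk1-Dio3 cluster, and Igf2r (1.47, SE 0.25) rose, or 4 adjusted over the list alone (adjusted p = 0.0342; adjusted p = 0.431 with an estimated correlation). The imprinted list was not called without untreated 2B1 (adjusted p = 0.192) or without 2i 5C5 (adjusted p = 0.0743).

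Markers of fibroblasts were higher under 2i. Of 25 tested, 5 rose and 0 fell, or 14 adjusted over the list alone: Tgfbi (2.55, SE 0.27), and the extracellular matrix genes Col6a2 (1.99, SE 0.30), Postn (1.96, SE 0.22), Col5a1 (1.59, SE 0.27) and Col1a2 (1.5, SE 0.26). The list was called (adjusted p = 5.85e-05; adjusted p = 0.377 with an estimated correlation). Of 13 interferon response genes, Usp18 (2.71, SE 0.39) and Ifit1 (2.28, SE 0.28) rose, or 7 adjusted over the list alone (adjusted p = 0.00646; adjusted p = 0.431 with an estimated correlation). Of 11 primed epiblast genes, the Nodal pathway genes Lefty2 (3.81, SE 0.29) and Lefty1 (3.37, SE 0.37) rose with Dnmt3b, or 6 adjusted over the list alone (adjusted p = 0.00337; adjusted p = 0.431 with an estimated correlation). Of 16 endoderm genes, Afp rose (1.13, SE 0.21), or 2 adjusted over the list alone. The list was called by camera (adjusted p = 0.00646, and adjusted p = 0.477 with an estimated correlation). Afp lost its call after quantile normalization and with arrays centred on the median, where 0 of the 16 rose. The primed list was not called without untreated 2B1 (adjusted p = 0.0986), nor the endoderm list without untreated 5C5 (adjusted p = 0.0787).

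Camera called 2 lists lower. Of 11 genes of p53 and senescence, Perp (-4.51, SE 0.61), Cdkn2a (-3.24, SE 0.29), which holds p16 and p19Arf, and the cell cycle inhibitor Cdkn1a (-2.46, SE 0.31) fell and 0 rose, or 5 adjusted over the list alone (adjusted p = 0.00266; adjusted p = 0.431 with an estimated correlation). Of 18 ERK targets, Dusp5 fell (-2.52, SE 0.34), or 2 adjusted over the list alone, and 2 of 18 were above 0 (adjusted p = 0.00646; adjusted p = 0.431 with an estimated correlation). Of 14 genes of the Ccr4-Not complex and its partners, 0 rose, and Btg2 (-3.15, SE 0.57) and Tob1 (-1.25, SE 0.23), antiproliferative proteins that bind the complex, fell, or 4 adjusted over the list alone. The list had a median of 0.12 and a mean of -0.37, and was not called (adjusted p = 0.357).

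In the lists not called, Krt18 rose (2.68) and Krt19 fell (-5.35) among 18 epithelial genes, or 2 and 1 adjusted over the list alone (adjusted p = 0.511). This list was called lower without untreated 2B1 (adjusted p = 0.000258) and higher without untreated 5C5 (adjusted p = 0.0247). Among 12 LIF and STAT3 targets, Tfcp2l1 (4.33), Klf5 (3.18), Gbx2 (2.55) and Pim1 (1.49) rose, and 2 fell adjusted over the list alone (adjusted p = 0.327). Axin2 (1.18) rose among 8 Wnt targets (adjusted p = 0.633), and Smad7 (1.31) rose and Id1 (-3.32) fell among 9 BMP targets (adjusted p = 0.221). Axin2 lost its call after quantile normalization and with arrays centred on the median, where 0 Wnt targets rose. Dcp2 (1.13) rose among 14 other mRNA decay factors (adjusted p = 0.546), Rhox6 (2.68) among 10 trophoblast genes (adjusted p = 0.229), and Tubb3 (2.85) rose and Sox11 (-2.39) fell among 9 neural genes (adjusted p = 0.588). With arrays centred on the median, 0 of the mRNA decay factors rose and 1 fell. Of the 4 mesoderm, 6 muscle and 5 macrophage and blood genes, 0 passed (adjusted p = 0.375, 0.229 and 0.588). The single tested members of the two-cell-stage, X inactivation and Y-linked lists had log2 fold changes of -0.61, -0.93 (Xist) and 0.14 (Eif2s3y), and did not pass.

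ESCs served as the reference for genuine pluripotent cells and were compared with the partial iPSCs (n = 2 against 2). Sex, line and, for EBRTcH3, strain differ along with the state. Zfp42 was higher in ESCs by 10.16 (SE 0.27, limma adjusted p = 0.000314) and Nanog by 8.72 (SE 0.30, adjusted p = 0.000512). Cd44, a hyaluronan receptor of mesenchymal cells, fell from 11.73 ± 0.01 (SD, n = 2) in partial iPSCs to 2.92 ± 0.00 in ESCs, a log2 fold change of -8.81 (SE 0.18, adjusted p = 0.000249). In ESCs it lay below the 25th percentile of the arrays (3.89), and the lower mean of 10 of the 20 named genes did so, which limits the size and rank of their fold changes. S100a4, a fibroblast marker, was lower by -7.28 (SE 0.27, adjusted p = 0.000512). The other highest were Rps4l (9.30), Sox2 (8.52), Dppa2 (8.23), Dppa5a (7.98), Mageb16 (7.84), Trap1a (7.83), Aard (7.55) and Dppa4 (7.52). The other lowest were Slc38a5 (-8.80), Mycn (-8.19), St3gal6 (-7.64), Gcnt3 (-7.38), Hbb-y (-7.37), Sptssb (-7.18), Hoxa9 (-7.13) and Sbspon (-6.86).

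The 3 probe sets of Mycn disagreed. The brightest read 14.29 and 14.26 in the partial clones, 12.18 and 12.62 in 2i iPSCs, and 6.13 and 6.05 in ESCs. Another read 8.35 and 8.13, then 9.99 and 10.38, then 10.80 and 10.84 in the same order, and the third read 6.49 and 6.43, then 7.62 and 7.96, then 8.58 and 8.51. The direction given for Mycn holds for the brightest probe set only.

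In this comparison 2015 of 12663 genes were called, 771 higher and 1244 lower in ESCs. Centring each array on its median removed a difference of -0.21 between the group medians and gave 1181 higher and 965 lower, so that 55.0% of called genes were higher in place of 38.3%. The same shift was 0.10 for 2i iPSCs against partial iPSCs and 0.31 for 2i iPSCs against ESCs. The counts were 371 higher and 792 lower without untreated 2B1, 487 and 856 without untreated 5C5, and 289 and 491 without either 2i array. They stood at 894 and 1434 without the Nanog-GFP line and 895 and 1209 without EBRTcH3.

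Of 20 naive pluripotency genes, 14 were higher and Klf4 was lower (-1.41, SE 0.30), or 16 and 1 adjusted over the list alone. The other Klf4 probe set was higher in ESCs (11.53 and 11.89) than in the partial clones (8.05 and 7.87). Examples were Tcl1 (7.46, SE 0.36), Tfcp2l1 (5.27, SE 0.43) and Dppa3 (3.83, SE 0.68). The list was called (adjusted p = 9.39e-13; adjusted p = 0.0857 with an estimated correlation). Of 16 general pluripotency genes, 8 were higher and Pou5f1 was lower (-0.86, SE 0.19), or 11 and 1 adjusted over the list alone. Lin28a stood at 7.48 (SE 0.49) and Foxd3 at 2.37 (SE 0.24). The list was called by camera (adjusted p = 6.63e-06, and adjusted p = 0.157 with an estimated correlation). With arrays centred on the median, 10 of these genes were higher and 0 lower, so that Pou5f1 lost its call. Of 11 primed epiblast genes, 5 were higher, or 7 adjusted over the list alone, among them Otx2 (5.47, SE 1.05) and Nodal (3.07, SE 0.56) (adjusted p = 0.00255; adjusted p = 0.543 with an estimated correlation). Of 15 germline genes, 9 were higher, or 13 adjusted over the list alone, such as Sycp3 (6.54, SE 1.21), a component of the synaptonemal complex (adjusted p = 2.68e-07; adjusted p = 0.415 with an estimated correlation). Of 10 genes of the DNA methylation machinery, 4 were higher, or 5 adjusted over the list alone, including Dnmt3l (7.06, SE 0.63) and Apobec2 (3.31, SE 0.59) (adjusted p = 0.00255; adjusted p = 0.232 with an estimated correlation). Of 16 imprinted genes, Meg3 (6.15, SE 0.67), Mirg (4.27, SE 0.51) and Rian (2.73, SE 0.35), noncoding RNAs of the same cluster, were higher and Dlk1 was lower (-2.02, SE 0.48), or 4 and 1 adjusted over the list alone. Dlk1 lost its call after quantile normalization and with arrays centred on the median, where 0 imprinted genes were lower. The imprinted list was called (adjusted p = 0.0144; adjusted p = 0.415 with an estimated correlation), but not without untreated 2B1 (adjusted p = 0.0732) or with arrays centred on the median (adjusted p = 0.0539).

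Fibroblast genes were lower in ESCs than in partial iPSCs. Of 25, 14 were lower and 0 higher, or 19 adjusted over the list alone, including the collagens Col3a1 (-5.06, SE 0.30) and Col1a2 (-5.05, SE 0.26) and the transcription factor Twist1 (-2.17, SE 0.21) (adjusted p = 3.79e-09; adjusted p = 0.212 with an estimated correlation). Of 18 ERK targets, 7 were lower, or 9 adjusted over the list alone, among them the immediate early genes Fos (-5.86, SE 0.81), Egr2 (-5.77, SE 0.39) and Ier3 (-4.06, SE 0.22) (adjusted p = 0.000133; adjusted p = 0.396 with an estimated correlation). Of 13 interferon genes, 6 were lower, or 9 adjusted over the list alone, such as Usp18 (-3.59, SE 0.39) and Ifit1 (-3.51, SE 0.28) (adjusted p = 0.000133; adjusted p = 0.374 with an estimated correlation). Of 11 genes of p53 and senescence, 4 were lower, or 6 adjusted over the list alone, including Igfbp3 (-3.81, SE 0.87) and Cdkn2a (-3.74, SE 0.29) (adjusted p = 0.0374; adjusted p = 0.549 with an estimated correlation). This list was not called without untreated 2B1 (adjusted p = 0.113) or without the Nanog-GFP line (adjusted p = 0.125).

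The Ccr4-Not list was not called in ESCs (adjusted p = 0.892). Of its 14 genes, Cnot3 was higher (0.78, SE 0.18), and Btg2 (-2.71, SE 0.57), Cnot6l (-2.09, SE 0.32), Cnot6 (-1.24, SE 0.25), Tob1 (-1.0, SE 0.23) and Tob2 (-0.87, SE 0.18) were lower, or 3 and 5 adjusted over the list alone. Cnot6 and Cnot6l are deadenylases of the complex. The median of the list was 0.08 and its mean -0.21. With arrays centred on the median, 3 of its genes were higher and 2 lower past the test. Dcp2 (1.34) was higher among 14 other mRNA decay factors (adjusted p = 0.0586, and 0.0164 without the Nanog-GFP line). Grhl2 (2.61) and Krt18 (3.58) were higher and Krt19 (-4.83) lower among 18 epithelial genes (adjusted p = 0.614, and 0.00232, higher, without untreated 5C5). Among 16 endoderm genes Pdgfra (-4.08), Dab2 (-2.85) and Lamb1 (-1.57) were lower (adjusted p = 0.491). Among 10 trophoblast genes 3 were higher (adjusted p = 0.134, and 0.0251 without EBRTcH3). Cdx1 (3.10) was higher among 4 mesoderm genes (adjusted p = 0.282), and Tubb3 (3.41) was higher and Sox11 (-1.93) lower among 9 neural genes (adjusted p = 0.614). Of 12 LIF targets 4 were higher and 2 lower (adjusted p = 0.276), of 9 BMP targets 1 and 1 (adjusted p = 0.464), and of 8 Wnt targets 2 and 1 (adjusted p = 0.614, median -0.02, mean 0.33). Tnnt2 (-2.57) was lower among 6 muscle genes (adjusted p = 0.790, median 0.10, mean -0.16), and Cd14 (-2.84) among 5 macrophage and blood genes (adjusted p = 0.740, median 0.43, mean -0.12, camera direction up). Of the 4 reprogramming genes Sox2 was higher and the other 3 lower, Klf4 on its brighter probe set only (adjusted p = 0.314, median -1.14, mean 0.49, camera direction down). With arrays centred on the median 1 was higher and 2 lower, and Pou5f1 lost its call. Eif2s3y, on the Y chromosome, was higher in the male ESCs (6.98, SE 0.32).

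The changes of the 2i iPSCs were set against those of ESCs, both relative to the partial iPSCs. Of the genes called in both comparisons, 347 were higher in both (27.3 for independent lists), 281 lower in both (30.6) and 23 opposite (63.0). The correlation across genes was 0.76, with 0.50 in 20 simulations of unchanged groups sharing the partial iPSC arrays, and 0.62 and 0.53 with the partial arrays split between the comparisons. The covariance was 1.01, with 0.08 in the simulations. Genes are not independent replicates. Of the 771 genes higher in ESCs, 761 (98.7%) moved the same way under 2i, with a median of 81.4% of the ESC difference (quartiles 61.1% and 98.2%). Of the 1244 genes lower in ESCs, 960 (77.2%) moved the same way, with a median of 42.2% (quartiles 4.6% and 75.7%). The genes were chosen on differences that share the partial iPSC arrays. In 20 simulations with ESCs as measured and 2i iPSCs unchanged, 59.6% and 57.8% moved the same way, with median shares of 4.8% and 3.4%. Naive pluripotency genes lay near equal change, and fibroblast genes such as Col1a2 were lower in ESCs (-5.05) and higher in 2i iPSCs (1.5).

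**Figure D2:**
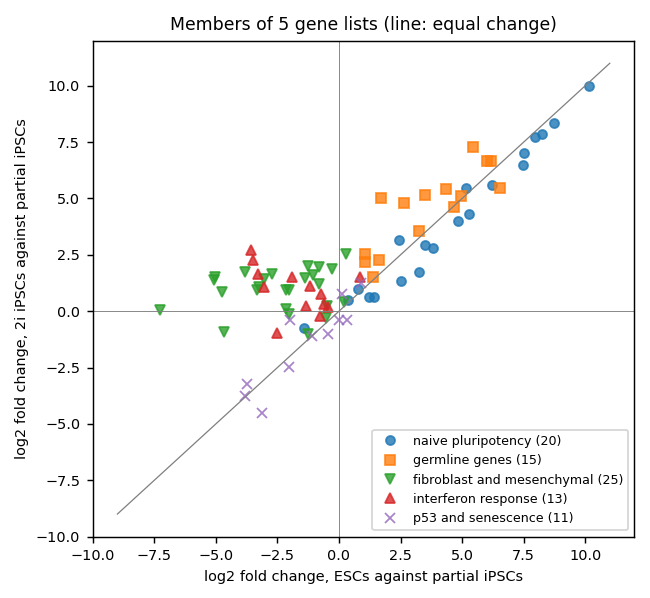
Log2 fold change against partial iPSCs of each tested member of 5 gene lists, in ESCs (x axis) and in 2i iPSCs (y axis), 1 point per gene, with a line at equal change. Naive pluripotency genes follow the line with Nanog at 8.72 and 8.37, and fibroblast genes lie left of 0 on the x axis except for a few, with S100a4 at -7.28.

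The direct comparison of 2i iPSCs with ESCs asked what still set converted cells apart (n = 2 against 2). Culture medium, sex, origin and, for EBRTcH3, strain differ together here. Cd44 stood at 11.20 ± 0.11 (SD, n = 2) in 2i iPSCs and 2.92 ± 0.00 in ESCs, a log2 fold change of 8.28 (SE 0.18, limma adjusted p = 0.000538). The lower mean of 7 of the 20 named genes lay below the 25th percentile, so their fold changes depend on the background. S100a4 was higher by 7.34 (SE 0.27, adjusted p = 0.00199), and the collagens Col1a2 by 6.56 (SE 0.26, adjusted p = 0.00199) and Col3a1 by 6.44 (SE 0.30, adjusted p = 0.00206). Nanog (-0.35, adjusted p = 0.637), Zfp42 (-0.15, adjusted p = 0.840) and Sox2 (-0.06, adjusted p = 0.945) did not pass the test. Vcam1 (7.60), Bgn (7.08), Ifi202b (6.79), Cavin2 (6.70), Efemp1 (6.59) and Mycn on its brightest probe set (6.31) completed the highest. Eif2s3y was lower in the 2i iPSCs of the female clones (-6.84, SE 0.32), as was Uba1y (-1.76), also on the Y chromosome. Others were Spink1 (-4.64, SE 0.21), Neurod1 (-3.00), Apela (-2.61), Fgfbp1 (-2.14), Stmn3 (-2.08), Iqcg (-1.72), D630023F18Rik (-1.64) and Fgf17 (-1.63).

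In all, 487 of 12663 genes were called, 467 higher and 20 lower in 2i iPSCs. After removal of the genes at least 2-fold higher in MEFs than in ESCs, a step added after seeing the data, 1 gene was higher and 2 were lower among 10196, with 941 at an unadjusted p below 0.05. This step uses the ESC values and took out 423 of the 467 higher genes and 0 of the 20 lower ones, so its counts do not measure how far the groups differ. Of the named lower genes, 8 lost their call with the same fold, such as Neurod1 (-3.00, SE 0.33, adjusted p = 0.0124 before and 0.108 after) over a set from which most called genes had been taken. The limma counts were 1 higher and 0 lower without 2i 2B1 (1119 genes at an unadjusted p below 0.05), 0 and 0 without 2i 5C5 (1062), 694 and 92 without the Nanog-GFP line, and 458 and 44 without EBRTcH3. Of the 20 genes named by the rule, 19 lost their call without 2i 2B1 and 20 without 2i 5C5. The lower count was 46 with arrays centred on the median and 39 after quantile normalization.

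Of 25 fibroblast genes, 18 were higher in 2i iPSCs and 0 lower, or 20 adjusted over the list alone, including Loxl1 (4.44, SE 0.28), Thy1 (4.32, SE 0.35) and Twist2 (3.09, SE 0.22) (adjusted p = 1.07e-21; adjusted p = 0.183 with an estimated correlation). The same genes define fibroblasts and many mesenchymal cells. Of 13 interferon genes, 7 were higher, or 8 adjusted over the list alone, such as Usp18 (6.30, SE 0.39), Ifit1 (5.79, SE 0.28) and Oasl2 (4.97, SE 0.46) (adjusted p = 2.71e-10; adjusted p = 0.289 with an estimated correlation). Of 16 endoderm genes, Pdgfra (4.66, SE 0.24), a receptor also found on fibroblasts, Afp (1.96, SE 0.21) and Lamb1 (1.23, SE 0.19) were higher, or 6 adjusted over the list alone (adjusted p = 0.000111; adjusted p = 0.544 with an estimated correlation). Of 18 ERK targets, Fosl1 (4.48, SE 0.49), Egr2 (3.77, SE 0.39), Ier3 (3.55, SE 0.22) and Ccnd1 (1.70, SE 0.24) were higher, or 5 adjusted over the list alone (adjusted p = 0.00340; adjusted p = 0.544 with an estimated correlation). The ERK list was not called without the Nanog-GFP line (adjusted p = 0.139).

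The remaining called lists had 0 members past the test over all genes. Naive pluripotency was lower by a median of -0.51 over 20 genes, with 0 adjusted over the list alone (adjusted p = 0.0164; adjusted p = 0.302 with an estimated correlation). General pluripotency was lower by a median of -0.24 over 16 genes, with 0 adjusted over the list alone (adjusted p = 0.0105; adjusted p = 0.302 with an estimated correlation). Other mRNA decay factors were lower by a median of -0.18 over 14 genes, with 0 adjusted over the list alone (adjusted p = 0.0349; adjusted p = 0.578 with an estimated correlation). Germline genes were higher by a median of 0.66 over 15 genes, with 1 adjusted over the list alone (adjusted p = 0.0432; adjusted p = 0.697 with an estimated correlation). None of these 4 lists was called without EBRTcH3, where the adjusted p was 0.0720 for both pluripotency lists, 0.635 for mRNA decay factors and 0.829 for germline genes. Quantile normalization also ended the calls of naive pluripotency (adjusted p = 0.166), general pluripotency and mRNA decay factors (adjusted p = 0.103 each), and centring on the median that of naive pluripotency (adjusted p = 0.0812). The mRNA decay list was not called without 2i 2B1 (adjusted p = 0.0918), nor the germline list without 2i 5C5 (adjusted p = 0.211) or without either partial array (adjusted p = 0.0623).

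Of 18 epithelial genes 0 passed (median -0.63, adjusted p = 0.0716). The epithelial list was called lower without the Nanog-GFP line (adjusted p = 0.0472), without 2i 5C5 (adjusted p = 0.0182) and without either partial array (adjusted p = 0.00744). Dlk1 (2.99) was higher among 16 imprinted genes (median -0.49, adjusted p = 0.127), Tnnt2 (3.20) among 6 muscle genes (adjusted p = 0.198), Cd14 (1.87) among 5 macrophage and blood genes (median -0.17, mean 0.03, adjusted p = 0.691), and Ccnd1 among 8 Wnt targets (adjusted p = 0.591). With arrays centred on the median Dlk1 lost this call. Of 14 Ccr4-Not genes (median -0.17, adjusted p = 0.263), 11 primed epiblast genes (adjusted p = 0.263), 10 trophoblast genes (adjusted p = 0.251) and 10 genes of the DNA methylation machinery (adjusted p = 0.168), 0 passed. Nor did any of 4 reprogramming genes (adjusted p = 0.834), 12 LIF targets (adjusted p = 0.490), 9 BMP targets (adjusted p = 0.545), 4 mesoderm genes (adjusted p = 0.525), 9 neural genes (median 0.20, mean 0.11, camera direction down, adjusted p = 0.857) or 11 genes of p53 and senescence (median 0.02, mean -0.03, adjusted p = 0.540). With arrays centred on the median, the neural median was -0.11. Without 2i 5C5 the imprinted, p53 and primed lists (adjusted p = 0.0227 each) and the trophoblast list (adjusted p = 0.0285) were called lower, and without EBRTcH3 the trophoblast list was (adjusted p = 0.0482).

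The clones themselves differed. Untreated 2B1 and 5C5 differed at least 2-fold in 1346 genes, 788 higher in 5C5 and 558 higher in 2B1, against 219 genes between the 2i iPSCs and 2002 between the ESC lines. These are differences of single arrays, without replicates, and rest on the clone labels. Among lists with at least 3 tested members, the epithelial list had the lowest median in 2B1 relative to 5C5 (-1.88, percentile 0.00 of random lists), with 13 of 18 genes at least 2-fold lower. Cdh1, the epithelial cadherin, read 7.40 in 2B1 and 11.87 in 5C5. Neural (-0.95), primed epiblast (-0.78), BMP (-0.41), ERK (-0.36) and general pluripotency genes (-0.23) were lower in 2B1, and interferon (0.72), fibroblast (0.43) and trophoblast genes (0.39) higher, each outside the middle 95% of random lists. Xist, the RNA that silences an X chromosome, read 5.44 in 2B1 and 13.49 in 5C5. The log2 changes under 2i of the clones had a correlation of 0.74 across genes. Under 2i, 1505 genes changed by at least 2-fold the same way in both clones and 75 in opposite ways.

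MEFs, a common starting cell of reprogramming, were compared with the untreated clones (1 array against 2, no replicates, no test). Postn, a matrix protein, was higher in MEFs by 8.0, and the growth factor Igf2 by 7.86, with Fhl1 (7.81), Myl9 (7.60) and Rps4l (7.46). Slc38a5 (-9.17), Pou5f1 (-8.97), Tdgf1 (-8.79), Mycn on its brightest probe set (-8.31) and Gcnt3 (-7.86) were lowest. In MEFs Tdgf1 (3.74) and Gcnt3 (2.77) lay below the 25th percentile of the array (3.89). Mycn read 14.29 in 2B1 and 14.26 in 5C5, close to the highest values of these arrays (14.56 and 14.52). The size and rank of these differences depend on the ends of the scale. The fibroblast list had a median of 3.63, with 22 of 25 genes at least 2-fold higher. Imprinted genes (2.23, 13 of 16 at least 2-fold higher), muscle genes (2.62) and endoderm genes (0.73) were also above the middle 95% of random lists. Epithelial genes (-1.74, 12 of 18 at least 2-fold lower), LIF targets (-1.49), DNA methylation machinery (-1.44), reprogramming genes (-2.60), interferon genes (-0.75) and ERK targets (-0.71) were below it, and naive pluripotency lay at percentile 2.57 with a median of -0.52. In all, 1254 genes were at least 2-fold higher and 1437 lower than in both clones.

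The next question was what each introduced factor changed in 2B1 partial iPSCs relative to empty vector (1 array each, no replicates, no test). The introduced genes were read first. On the Cnot2 array the 6 Cnot2 probe sets differed from vector by -0.32 to 0.08, on the Cnot3 array the Cnot3 probe sets by 0.06 and 0.30, and on the Trim28 array the Trim28 probe sets by -0.33 and -0.01. Nanog read 3.12 on the Nanog array and 4.11 on the vector array. Cnot1 had 0 probe sets of its own and 2 shared with another gene. Probes outside an introduced cDNA do not detect it, and where the probes lie in the cDNAs is not given in the sources used here, so these values check no label. Nanog, Zfp42 and Sox2 stayed near background on all 7 transduced arrays. Klf4 was lower on 1 of its probe sets by -2.02 (Cnot1), -1.55 (Cnot2), -2.58 (Cnot3), -2.06 (Trim28) and -2.55 (Cnot123), against 0.10 with Nanog. On its other, brighter probe set these were -0.91, -0.61, -0.94, -0.64 and -1.34, against -0.02. Across the blocks, the dimmer probe set read 8.05 in untreated 2B1 and 10.08 with vector, so it was also below vector without a factor. The brighter one read 12.11 in untreated 2B1 and 11.54 with vector.

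Epithelial genes were lower with each factor. The median over 18 genes was -1.25 with Cnot1, -1.10 with Cnot2, -1.03 with Cnot3, -0.72 with Trim28, -1.75 with Cnot123 and -0.51 with Nanog, each at percentile 0.00 of random lists. On the Cnot123 array 15 of the 18 were at least 2-fold lower, 10 with Cnot1 and 10 with Cnot2, 9 with Cnot3, 4 with Trim28 and 4 with Nanog. Cdh1 read 10.17 with vector, 7.02 with Cnot1, 8.59 with Cnot2, 8.35 with Cnot3, 9.50 with Trim28, 9.66 with Nanog and 3.34 with Cnot123. Xist read 13.08 with vector, 8.88 with Cnot1, 11.19 with Cnot2, 10.55 with Cnot3, 12.50 with Trim28, 13.01 with Nanog and 4.79 with Cnot123. Untreated 2B1, which comes from the other normalization block, had an epithelial median of -1.34 relative to vector, a Cdh1 level of 7.40 and an Xist level of 5.44.

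BMP targets were lower with Cnot1 (-0.68), Cnot2 (-0.50), Cnot3 (-0.89), Trim28 (-0.58) and Cnot123 (-1.29, 7 of 9 at least 2-fold lower), and ERK targets with the same factors (-0.36, -0.27, -0.54, -0.35 and -0.50), all below the middle 95% of random lists. Without a factor, and across the blocks, untreated 2B1 had medians of -0.42 for BMP and -0.11 for ERK targets relative to vector, below the middle 95% too. Fibroblast genes were higher, by medians of 0.37 with Cnot1, 0.31 with Cnot2, 0.21 with Cnot3, 0.20 with Trim28, 0.57 with Cnot123 and 0.14 with Nanog, all above it. Of the 25, those at least 2-fold higher and lower were 2 and 5 with Cnot1, 1 and 3 with Cnot2, 2 and 3 with Cnot3, 1 and 0 with Trim28, 8 and 4 with Cnot123, and 0 and 2 with Nanog. Across the blocks, untreated 2B1 had a fibroblast median of 1.27 relative to vector, above that of each factor. Naive pluripotency genes had medians of 0.38 with Cnot1 (percentile 99.98) and 0.16 with Cnot2 (97.97), and those of p53 and senescence 0.48 (99.94) and 0.40 (99.97). Across the blocks, untreated 2B1 had higher medians relative to vector, 0.60 for naive pluripotency and 0.92 for p53 and senescence. LIF targets were lower with Cnot123 (-0.49), Cnot3 (-0.26) and Trim28 (-0.23), and reprogramming genes with Cnot3 (-0.49) and Trim28 (-0.31). Trim28 also had lower interferon (-0.31) and Ccr4-Not genes (-0.17) and higher neural genes (0.23). Nanog had higher interferon (0.31), imprinted (0.17) and ERK genes (0.09). The other lists with at least 3 tested members lay within the middle 95% on these arrays. The difference between array medians removed by centring was -0.16 (Cnot1), -0.12 (Cnot2), -0.15 (Cnot3), -0.09 (Trim28), -0.21 (Cnot123) and -0.07 (Nanog), and 0.24 for untreated 2B1.

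**Figure D3:**
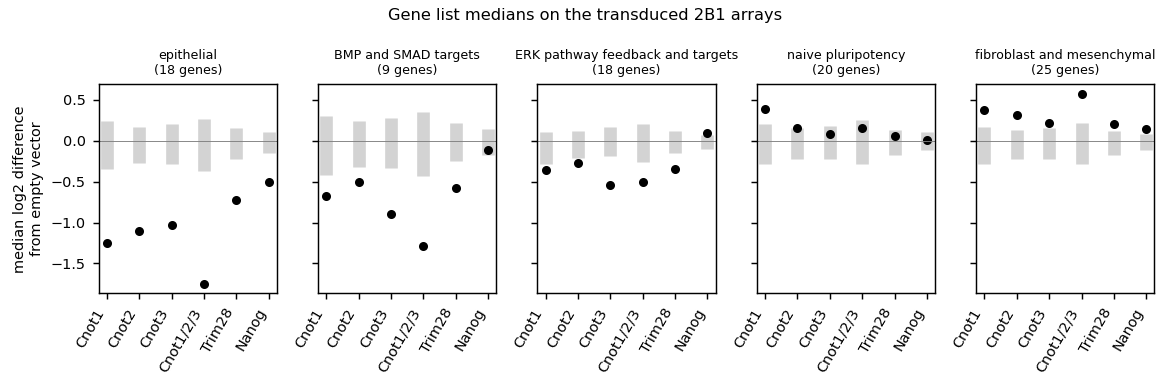
Median log2 difference from empty vector (y axis) of 5 gene lists on the 6 arrays with an introduced factor (x axis), 1 point per array. Grey bars span the middle 95% of 10000 random lists, and the epithelial medians lie below them on all 6 arrays, from -0.51 with Nanog to -1.75 with Cnot1, Cnot2 and Cnot3 combined.

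Nat8f3 was among the 5 highest genes with Cnot1, Cnot2 and Cnot3, and Tlcd4 among the 5 lowest. Across the blocks, both lay on the same side of vector in untreated 2B1, without a factor. Nat8f3 read 10.29 there and 7.60 with vector, and Tlcd4 2.90 and 7.62. Cnot1 had Sulf1 (2.90), Nat8f3 (2.89), Rgs7 (2.88), Sectm1a (2.81) and Dner (2.81) highest and Tenm2 (-5.36), Adcy8 (-5.31), Nell1 (-5.13), Tlcd4 (-4.67) and Calcrl (-4.53) lowest. Cnot2 had Nat8f3 (2.74), Ccdc141 (2.47), Vat1l (2.46), Foxd1 (2.46) and Sectm1a (2.46) highest and Tlcd4 (-3.41), 2310011E23Rik (-3.29), Foxa1 (-3.17), Calcrl (-3.14) and Adgrb3 (-3.14) lowest. Cnot3 had Nat8f3 (3.05), Foxd1 (2.76), Ddc (2.72), 2610300M13Rik (2.61) and 1700042O10Rik (2.58) highest and Tlcd4 (-4.31), Nell1 (-3.84), Kcnt2 (-3.67), P2rx3 (-3.59) and Cdh4 (-3.58) lowest. The Cnot123 array had 2610300M13Rik (4.15), Foxd1 (3.56), Tfap2d (3.07), Nr0b1 (3.01) and Zmat4 (3.00) highest and Xist (-8.30), Cdh1 (-6.82), Tenm2 (-6.50), Slc6a15 (-6.28) and Nell1 (-5.93) lowest. On this array Cdh1 (3.34), Tenm2 (2.99), Slc6a15 (3.06) and Nell1 (2.55) lay below the 25th percentile (3.66). The size and rank of their differences therefore depend on the background, as do those of other genes at such levels, for example Tlcd4 with Cnot1 (2.95). Trim28 had 2610300M13Rik (2.37), G530011O06Rik (2.34), Lama1 (2.19), Zmat4 (2.01) and Tfap2d (2.00) highest and Ugt8a (-2.66), Fosb (-2.55), Nell1 (-2.39), Ptpru (-2.39) and Lhx2 (-2.33) lowest. Nanog had Trap1a (4.02), Tgm3 (3.37), Fam110c (2.99), Eomes (2.99) and Ldb2 (2.77) highest and Cdh9 (-3.59), Aldh1a2 (-3.40), Iqsec3 (-2.82), Cldn9 (-2.62) and Adcy8 (-2.31) lowest. Trap1a read 3.46 with vector, below the 25th percentile of that array (3.55), so the size and rank of its difference depend on the background.

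Genes at least 2-fold higher and lower than vector numbered 525 and 743 with Cnot1, 363 and 492 with Cnot2, 315 and 657 with Cnot3, 122 and 193 with Trim28, 471 and 1067 with Cnot123, and 71 and 110 with Nanog. Untreated 2B1 differed from vector in 2125 genes, 1533 higher and 592 lower, across the 2 normalization blocks. With arrays centred on the median the counts were 702 and 596 for Cnot1, 491 and 406 for Cnot2, 434 and 513 for Cnot3, 156 and 147 for Trim28, and 812 and 803 for Cnot123. With untreated 2B1 as the control, again across the blocks, they were 191 and 1138 for Cnot1, 274 and 1133 for Cnot2, 188 and 1132 for Cnot3, 408 and 1436 for Trim28, 142 and 1444 for Cnot123, and 559 and 1548 for Nanog.

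The differences from vector were set against the difference between the untreated clones. Across genes the correlation with untreated 2B1 minus untreated 5C5 was 0.70 with Cnot1, 0.68 with Cnot2, 0.69 with Cnot3, 0.45 with Trim28, 0.62 with Cnot123 and 0.18 with Nanog. Of the 1268 genes at least 2-fold from vector with Cnot1, 57.3% also differed at least 2-fold between the clones, and 715 lay toward 2B1. These shares were 65.7% with Cnot2, 59.9% with Cnot3, 59.4% with Trim28, 43.4% with Cnot123 and 57.5% with Nanog.

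The last comparison asked whether the factors moved 2B1 cells in the direction that 5C5 cells took under 2i. Of 2646 genes at least 2-fold changed in 5C5, 1422 were higher and 1224 lower under 2i. The share moving the same way relative to vector was 64.7% with Cnot1 (exact 95% interval 62.8% to 66.5%), 62.8% with Cnot2 (60.9% to 64.6%), 63.2% with Cnot3 (61.3% to 65.0%), 66.1% with Trim28 (64.2% to 67.9%), 67.6% with Cnot123 (65.8% to 69.4%) and 59.4% with Nanog (57.5% to 61.3%). The slopes on the 5C5 change were 0.14 with Cnot1, 0.096 with Cnot2, 0.114 with Cnot3, 0.073 with Trim28, 0.191 with Cnot123 and 0.043 with Nanog. Across the blocks, untreated 2B1 relative to vector had a share of 68.4% (66.6% to 70.2%) and a slope of 0.209, and 2i 2B1 a share of 95% and a slope of 0.935. With untreated 2B1 as the control, also across the blocks, the shares were 41.2% with Cnot1, 36.2% with Cnot2, 39.0% with Cnot3, 37.4% with Trim28, 43.7% with Cnot123 and 34.2% with Nanog. Over 712 genes called in 2i iPSCs against partial iPSCs that moved in both clones, a set added after seeing the data, the shares were 52.9%, 50.4%, 53.2%, 59.8%, 59.4% and 55.8% in the same order.

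The 6 arrays share the vector array as control. The correlation of their differences across genes had a median of 0.71 over 15 pairs (0.23 to 0.94) and of 0.84 over the 6 pairs among Cnot arrays (0.73 to 0.94), where unchanged simulated arrays gave 0.50. For Cnot1 and Cnot2 it was 0.94, with a covariance of 0.340 against 0.047 simulated, and for Cnot1 and Nanog 0.27, with 0.057. The simulated spread came from the difference between the Nanog and vector arrays, so pairs with Nanog have no independent reference. A simulated correlation of 0.50 follows from equal spread around a shared control, whatever the size of that spread. For Cnot1 and Cnot2, 337 genes were at least 2-fold higher on both arrays (15 for independent lists) and 472 lower on both (28.9). With untreated 2B1, from the other block, as control of Cnot2, these were 46 and 85. With that control for the first array of each pair in turn (in the order Cnot1, Cnot2, Cnot3, Trim28, Cnot123, Nanog) the median correlation was -0.05, for the other array -0.43, and over all 30 values -0.18. Part of the excess over both references may come from the shared vector array, which is a single array and cannot be split. On all 4 Cnot arrays, 155 genes were at least 2-fold higher and 402 lower. Of these, 114 and 283 differed at least 2-fold the same way between untreated 2B1 and 5C5, and 39 and 119 differed by less than that between the clones. Examples of the latter, chosen after their values were seen, were Gdf3 (mean difference -2.86), a growth factor of pluripotent cells, Tenm3 (-3.66) and Ugt8a (-3.07) among the lower genes and Cd80 (2.02) and Nr5a2 (1.83), a nuclear receptor that drives Pou5f1, among the higher. In untreated 2B1, from the other normalization block, these genes lay on the same side of vector as on the Cnot arrays: Gdf3 read 10.21 with vector and 4.84 in untreated 2B1, Tenm3 8.38 and 3.66, Ugt8a 5.86 and 3.01, Cd80 5.94 and 7.74, and Nr5a2 3.99 and 6.66.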

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

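Of the tests in this part, that of 1 X chromosome in 2B1 against 2 in 5C5 was chosen after the result was seen.

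Of 273 listed genes, 6 moved at least 2-fold in opposite directions when the 2 clones were put under 2i. Each clone has 1 array per condition, so these differences between the clones were not tested. The epithelial genes Cldn7 (log2 change 2.38 in 2B1 and -1.70 in 5C5, a difference of 4.08), Epcam (1.35 and -1.37, difference 2.72) and Krt8 (1.54 and -2.97, difference 4.50) were higher under 2i in 2B1 and lower in 5C5. The imprinted gene Phlda2 (3.11 and -1.38, difference 4.49) and the epiblast gene Sox3 (1.31 and -1.14, difference 2.46) went the same ways. Xist had the largest difference of the 6, with 2.49 in 2B1, -4.36 in 5C5 and a difference of 6.85. For all 6 the 2i iPSCs of the clones lay closer together than the untreated clones, as with Krt8 at 5.43 and 9.59 untreated and at 6.97 and 6.62 under 2i. This is not particular to them. Over all tested genes, 1346 differed at least 2-fold between the untreated clones and 219 between the 2i iPSCs. Moves in opposite directions, by which the 6 were picked, also change the gap between the clones by rule.

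Xist read 5.44 in untreated 2B1 and 13.49 in untreated 5C5, although both clones carry female labels. Array quality was checked on 248 genes as bright as Xist in 5C5, whose median difference between the clones was -0.02. Both arrays lie in 1 normalization block, where quantile normalization aligns their bright ends, so this check cannot decide on array quality. The presence of 2 active X chromosomes in untreated 2B1 is argued against by X-linked genes. They lay only 0.05 above the autosomal median in untreated 2B1 relative to 5C5, at the upper end of random gene sets (-0.05 to 0.05). The explanation of 1 X chromosome in the 2B1 cells against 2 in the 5C5 cells stays open: 4 transduced 2B1 arrays (vector 13.08, Nanog 13.01, Trim28 12.50 and Cnot2 11.19), in the other normalization block, read Xist at least 4-fold above both male ESC arrays (8.42 and 9.03), which goes against it for the clone as a whole, but 5C5-like cells on these arrays, which the tests did not exclude for vector, could bring that Xist. X-linked genes were lower in 2i 2B1 than in 2i 5C5 (-0.19 from the autosomal median, random sets -0.03 to 0.03), as they would also be if the silent X had been reactivated in 5C5 only. From untreated to 2i, X-linked genes stood 0.23 from the autosomal median in 5C5 and -0.06 in 2B1 (random sets -0.06 to 0.07 for each). These are differences of single arrays, and no other biological explanation was tested.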

How the results depend on the processing

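Several alternatives were chosen after the results were seen. These were removal of the genes high in MEFs, removal of genes that differ between the clones, and the set of called genes that moved in both clones. Others were the MEF count with 1 clone left out, other scalings of the mixture test of the vector array and, for counts and single genes, untreated 2B1 as control. The cause was not tested unless fewer arrays, fewer genes or another minimum make it plain.

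In the limma comparisons, the 60 named genes all passed with quantile normalization, centring on the median and a 2-fold minimum. For 2i iPSCs against partial iPSCs, the 4 compared arrays alone gave 847 higher and 549 lower, removal of genes high in MEFs left 197 lower, and the clone as a replicate block, which pairs the arrays of a clone, gave 183 higher and 114 lower, ended the call of Dazl and changed no call of a gene list. For ESCs against partial iPSCs, centring gave 1181 higher, the 4 arrays alone 289 and 491, and removal of genes high in MEFs 273 lower. That removal uses the ESC values and itself took out 859 of the 1244 lower genes. For 2i iPSCs against ESCs, quantile normalization gave 39 lower and centring 46, and removal of genes high in MEFs left 1 higher and 2 lower (941 at an unadjusted p below 0.05), where the step itself took out 423 of 467 higher genes because it uses the ESC values. With an estimated correlation camera called 0 lists in each of the 3 comparisons. This loss does not measure correlation between list genes alone. In 2i iPSCs against partial iPSCs it included lists whose estimated correlation lay below the fixed 0.01. These were naive pluripotency (-0.041), general pluripotency (-0.017) and DNA methylation machinery (-0.004). Leaving out 1 array gave 31 to 847 higher and 11 to 549 lower for 2i iPSCs against partial iPSCs, 289 to 895 and 491 to 1434 for ESCs against partial iPSCs, and 0 to 694 and 0 to 92 for 2i iPSCs against ESCs. Lists called ranged from 10 to 11, 8 to 11 and 5 to 12. The MEF count ranged from 3674 to 3951 with 1 clone left out, in place of 2691 with both, since fewer arrays have to differ. Signal near background limits genes that are dim in both groups, and 2 arrays per group limit changes under a log2 of 2.

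For the transduced arrays, the mean of vector and untreated 2B1, which spans the blocks, was 1 other control. In the order Cnot1, Cnot2, Cnot3, Cnot123 and Nanog, it gave 695, 416, 503, 1024 and 600 genes at least 2-fold apart. A minimum of 0.58 gave 3043, 2197, 2430, 3480 and 665, with 1281 for Trim28. Without genes that differ between the clones there were 541, 293, 390, 870 and 77, with 128 for Trim28. With untreated 2B1, from the other block, as control there were 1407 for Cnot2, 1844 for Trim28 and 2107 for Nanog. The share of genes moving as in 5C5 under 2i, in the order Cnot1, Cnot2, Cnot3, Trim28, Cnot123 and Nanog, turned to 41.2%, 36.2%, 39.0%, 37.4%, 43.7% and 34.2% with that control. It was 57.9%, 55.3%, 61.3%, 58.6%, 62.4% and 54.5% over genes from ESCs against 5C5. Over genes called in 2i iPSCs against partial iPSCs that moved in both clones it was 52.9%, 50.4%, 53.2%, 59.8%, 59.4% and 55.8%. With a minimum of 2 log2 it was 67.3% (Cnot1), 66.2% (Cnot3), 69.5% (Cnot123) and 61.8% (Nanog). The median correlation between the 6 arrays turned to -0.18 with untreated 2B1, from the other block, as control for 1 array of each pair. This was over both choices of that array (-0.05 with the first, -0.43 with the other).

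With untreated 2B1, from the other block, as control, 7 of 60 named genes kept their sign and about their size. Another 30 kept their sign with a changed size, and 23 took the other sign. These were Tenm2 0.78, Adcy8 0.60 and Tlcd4 0.05 (Cnot1), Vat1l -0.99, Tlcd4 1.31, 2310011E23Rik 0.51, Foxa1 0.85, Calcrl 0.06 and Adgrb3 1.92 (Cnot2), and Ddc -0.03, 2610300M13Rik -0.01, Tlcd4 0.41, Nell1 0.64, Kcnt2 0.29 and Cdh4 0.20 (Cnot3). Others were 2610300M13Rik -0.25, Lama1 -0.80, Ugt8a 0.19, Nell1 2.08 and Ptpru 0.17 (Trim28), Slc6a15 0.28 (Cnot123), and Cdh9 0.07 and Adcy8 3.61 (Nanog). Some of these differences were smaller than 0.24, the difference between the medians of untreated 2B1 and vector, so their sign may rest on the offset between the blocks. With the mean of both controls, also across the blocks, 9 of the 60 kept their sign and about their size, and 50 changed in size. Adcy8 on the Nanog array took the other sign, with 0.65. Over the alternatives, including those that leave out an array, 113 of the 197 values that answer a comparison kept their direction and range.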

Other observations

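In this part the tests of fibroblasts in the 2i cultures, of unconverted partial iPSCs, of 5C5 cells on the vector array and of separate normalization were chosen after the result was seen, as was the repeat of the mixture test without the offset between the blocks, while the mixture test itself was not.

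Noncoding RNAs of the imprinted Dlk1-Dio3 cluster, looked at after their values were seen, lay lowest in partial iPSCs. Meg3 read 5.76 and 5.64 in the untreated clones, 9.77 in 2i 2B1, 11.47 in 2i 5C5, 11.26 and 12.46 in the ESC lines and 12.77 in MEFs. Mirg read 4.83 and 4.53, then 6.84 and 7.61, then 8.30 and 9.60, and 8.74 in MEFs, and Rian 4.49 and 4.69, then 5.64 and 6.46, then 7.05 and 7.59, and 8.52. Unlike Meg3, neither Mirg (limma adjusted p = 0.0535) nor Rian (0.0795) passed the test for 2i iPSCs against partial iPSCs. On the 7 transduced arrays, in the other normalization block, Meg3 lay between 5.34 and 5.97. Dlk1, a protein-coding gene of the cluster, took another course, with 7.90 and 7.08 in the untreated clones, 8.11 and 8.80 under 2i, and 5.97 and 4.96 in ESCs.

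The ERK target list was called lower in 2i iPSCs than in partial iPSCs (adjusted p = 0.00646, but 0.431 with an estimated correlation) and Dusp5 fell, but some of the best known feedback genes, picked after their values were seen, did not pass. These were Dusp6 (-0.77, SE 0.71), Etv5 (-0.60, SE 0.24), Spry4 (-0.39, SE 0.97), Etv4 (-0.34, SE 0.27) and Spry2 (0.35, SE 0.28), with limma adjusted p from 0.215 to 0.848. With 2 arrays per group, changes of this size are mostly beyond the reach of the test. The ESC lines differed in such genes: Egr1 read 4.85 in the Nanog-GFP line and 10.13 in EBRTcH3, Spry4 6.69 and 9.78, and Dusp6 8.10 and 10.23. Egr1 read 12.17 and 12.34 in the 2i iPSCs.

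Fibroblast genes stood higher in 2i iPSCs than in ESCs, by 7.34 for S100a4 and 6.56 for Col1a2. Partial iPSCs left unconverted in the 2i cultures are argued against as the whole source, because 4 list members, Col1a2, Col5a1, Col6a2 and Postn, were higher in 2i iPSCs than in partial iPSCs past the test. If fibroblasts like those of the MEF array were the whole source, the list would require a share of 14.4% of the RNA. Of 50 genes abundant in MEFs and low in ESCs and partial iPSCs, 5 lay more than 10-fold below the level required on both 2i arrays. They were Igf2 at 5.77 (10.74 required), Myl9 at 6.01 (10.32 required), Actg2, Cthrc1 and Tagln. These 5 genes argue against that source. The bound for them, at least 5 of the 50, was set after the values were seen and equals the count, so passing it is no test. A bound set earlier, more than 25% of the 50 genes over 2 log2 below, left this undecided (28.0%, exact 95% interval 16.2% to 42.5%), but at the lower quartile of the share over the list, 7.1%, 7 genes still lay more than 4-fold below. A smaller share of such cells, fibroblasts in another state and fibroblast genes expressed by the 2i iPSCs themselves stay open, and no biological explanation was tested.

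The array with empty vector in 2B1 resembled untreated 5C5 more than untreated 2B1. Over 136 genes at least 4-fold higher in untreated 2B1, its median position, set across the normalization blocks, was 0.34 on a scale from 0 (5C5) to 1 (2B1), with a bootstrap interval over genes of 0.30 to 0.44 (0.43 with arrays centred on the median), which argues against an array that holds only cells like untreated 5C5, since these would lie at 0. Separate normalization of the blocks is argued against by a correlation of 0.62 within the block between the Cnot1, Cnot2 and Cnot3 array minus vector and the difference of the clones. A mixture of cells like the 2 untreated clones stays open: its shares of 5C5-like RNA from the gene sets higher in 5C5 and in 2B1 were 54.6% and 84.6%, 30.1 points apart (24.5 to 35.8) and past the bound of 20 set beforehand, but 5.4 points apart (-0.8 to 11.7) with arrays centred on the median and 9.9 (1.7 to 18.2) after quantile normalization, so that the distance depends on the offset between the blocks. A mixture and a change of the vector cells in culture or after infection cannot be told apart here, a wrong label of the untreated 2B1 array, on which the clone differences, the clone pairing and the Xist comparison rest, was not tested, and it stays open whether a difference from vector belongs to the factor or to the vector array.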
